A study of Caenorhabditis elegans with 12 samples.

How the data were processed

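RNA was measured in whole N2 hermaphrodites of Caenorhabditis elegans by polyadenylated-RNA sequencing (TruSeq RNA v2). The worms had fed on bacteria with the empty RNAi vector L4440 or with a bcat-1 RNAi vector and were collected at an age of 1 day or 2 days. There were 12 libraries in 4 groups, 3 libraries per group. The labels do not say whether libraries are separate cultures, so every p-value measures only the spread between these samples. Replicates carry no number in the labels, and the numbers used here name libraries and pair nothing.

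Per the labels, the authors called bases with bcl2fastq 1.8.4, aligned reads to WBcel235 with STAR 2.4.1d and counted reads per gene with featureCounts 1.4.6-p4. The deposited table of counts holds whole-number read counts per gene for the 12 libraries, and every value of the report comes from it. The authors' second table holds RPKM (reads scaled to gene length and sequencing depth). In the RPKM table the divisor of a value followed its place in the table, by line and column together, and not its library. 18 divisors repeated down the lines and on into the next column. Over 5371 genes with over 500 counts in every library, these divisors left an SD of 2.1e-05 on the log2 scale, and 1 divisor per library left 0.195. The divisors spanned 0.566 on the log2 scale, and the divisor of a gene changed between libraries. These RPKM values are therefore not scaled to their own library, and they were used only in alternatives planned before the data were examined. The annotation release, the strand setting and the treatment of reads that map to several places are not stated in the labels, and gene symbols and positions come from Ensembl annotation 115.

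The count table held 46748 genes, of which 46449 were in the annotation, 43693 had a symbol and 21649 had no count in any library. Library totals ran from 29291731 to 43855795 counts. Confidence intervals of a single library's share are Wilson intervals at 95%, and intervals cover counting error only. A transcript with no count in a library could still make up 3 counts of its total.

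Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes passed filterByExpr by group, which left 14567 genes. Library sizes were scaled with TMM factors, and CPM values use these scaled sizes. 1 quasi-likelihood model with a mean for each of the 4 groups was fitted to the 12 libraries, with 8 residual degrees of freedom and a common dispersion of 0.04. These contrasts were tested with the quasi-likelihood F test: bcat-1 RNAi against L4440 at day 1, the same at day 2, the difference between those effects, and day 2 against day 1 on each food. Tests are two-sided, and p-values were adjusted by Benjamini-Hochberg over all genes tested, with a threshold of 0.05. Errors are SD for CPM (n = 3 per group) and SE for log2 fold changes.

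44 gene lists were written before the data were examined, of pathways, cell type markers and complexes, and 43 had at least 3 tested members. Of 1677 written list members, 1658 were in the count table. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, again with an estimated correlation, and with fry. P-values of lists were adjusted over the lists of a comparison. Fry asks whether the genes of a list move one way on balance and does not compare them with other genes.

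Named genes followed a rule written before the data were examined. It took bcat-1, and for the RNAi effect at each day the 10 genes with the largest change in each direction among those past the test, with a mean of at least 2 CPM and groups that did not overlap. It took 6 in each direction for each age comparison, 5 in each direction for the difference between days, and up to 4 members past the test per described list, those with the smallest adjusted p. Where a gene was chosen after its values were seen, the text says so.

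Alternatives planned before the data were examined were RLE factors, library size only, upper-quartile factors, DESeq2 1.42.0, limma-voom, no filter (25099 genes), a stricter filter of 1 CPM and 50 counts (12191 genes), a test against a fold of 1.5, limma-trend on log2(RPKM + 1) and log2(RPKM + 0.1), a fit of only the compared groups, and leaving out each of the 12 libraries in turn. Alternatives added after the data were seen were leaving out the 22 rRNA genes, leaving out both libraries with over 5% of counts in rRNA genes, and adding 1 or 2 surrogate variables (sva 3.50.0, which estimated 2). No library was left out of the values reported as the result.

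Other splits of the libraries were counted: all 10 splits for each comparison of 3 against 3, and 100 drawn splits (seed 30) for the difference between days. The edgeR test was tested on simulated data with 200 changed genes (seed 20): at day 2, 73.1% of genes changed 2-fold and 40.3% of genes changed 1.5-fold were called, and 2.7% of calls were false. Over the comparisons, with 1 draw each, false calls ran from 2.2% (difference between days) to 7.1% (day 1). Counts were drawn gene by gene from the dispersions of the edgeR fit, with no structure shared between genes. These shares may therefore not hold for the real libraries. Relations across samples used Pearson and Spearman coefficients with exact permutation p-values in R, and list overlaps used one-sided Fisher's exact tests. Wilson intervals came from scipy 1.17.1. Tables and figures were made in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6. The count table held 0 columns of other samples, and no reads were aligned anew because none were used here.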

Results

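Gene expression was measured in whole C. elegans hermaphrodites that had fed on bacteria carrying the empty vector L4440 or a bcat-1 RNAi vector, at day 1 and at day 2, with 3 libraries in each of the 4 groups. BCAT-1 is the aminotransferase that starts the breakdown of leucine, isoleucine and valine. At day 1 the L4440 libraries held 41636334, 43855795 and 30318777 counts (replicates 1, 2 and 3) and the bcat-1 libraries 38276467, 33995773 and 29291731. At day 2 the L4440 libraries held 41060319, 32710967 and 29885578 counts and the bcat-1 libraries 36136970, 41495675 and 29483982. The ribosomal RNA gene rrn-3.1 took 41.4% of counts (Wilson interval 41.397% to 41.433%) in the library labelled bcat-1 day 2 replicate 3. It took 6.72% (6.714% to 6.731%) in L4440 day 2 replicate 3 and 2.48% in bcat-1 day 1 replicate 3, and rRNA genes together took 0.07% to 0.97% in the other 9 libraries.

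The transcript of the RNAi target is a check of the labels and of the RNAi. The bcat-1 transcript (WBGene00001149, chromosome X, 12877480 to 12880328 in WBcel235) stood at 170 ± 12.4 CPM on L4440 and 21.5 ± 4.85 CPM on bcat-1 RNAi at day 1 (mean ± SD, n = 3 per group). At day 2 it stood at 138 ± 20.3 CPM on L4440 and at 13.9 and 17.3 CPM in bcat-1 replicates 1 and 2, but at 329 CPM in the library labelled bcat-1 day 2 replicate 3. Over all 12 libraries the log2 fold change was -2.98 (SE 0.94, adjusted p = 1) at day 1 and -0.21 (SE 0.86, adjusted p = 0.952) at day 2, and neither passed the edgeR test. Every bcat-1 library of day 1 lay below every L4440 library of day 1. Without that 1 library bcat-1 was 8-fold lower at day 1 (-3.0, SE 0.17, adjusted p = 2.24e-05) and 8.9-fold lower at day 2 (-3.15, SE 0.20, adjusted p = 8.52e-05). Over the alternatives the adjusted p ran from 2.24e-05 to 1 at day 1 and from 8.52e-05 to 1 at day 2. This range leaves out the planned fit of only the compared groups. In that fit bcat-1 was the 1 gene called at day 1, and 0 genes were called at day 2. The day 2 log2 value was 0.32 without bcat-1 day 2 replicate 1 and 0.30 without replicate 2. Reads of the fed double-stranded RNA can map to this gene too, so its level is not a measure of knockdown alone.

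**Figure D1:**
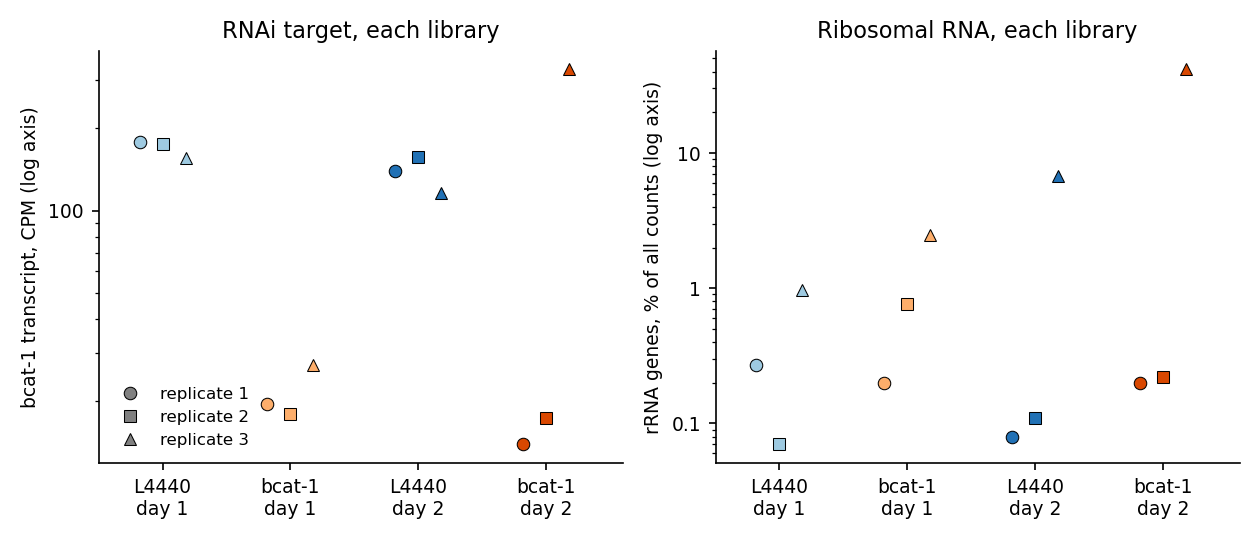
bcat-1 level (CPM, log axis) and share of counts in rRNA genes (%, log axis) in each of the 12 libraries, by group, with the replicate number as the marker. The library labelled bcat-1 day 2 replicate 3 holds 329 CPM of bcat-1 and 41.46% of its counts in rRNA genes.

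The comparison at day 1 asks which transcripts differ under bcat-1 RNAi at the earlier age. No gene passed the test, and the genes with the smallest adjusted p, chosen after their values were seen, were C14C6.5 (log2 0.86, SE 0.12) and hrg-7 (1.21, SE 0.17), each with adjusted p = 0.116. The acyl-CoA dehydrogenase gene acdh-2 stood at 30.7 CPM on L4440 and 6.52 CPM on bcat-1 RNAi (log2 -2.23, SE 0.35, adjusted p = 0.173), and the transsulfuration gene cth-1 had a log2 value of 1.03 (adjusted p = 0.392). Genes of the one-carbon and methionine cycle, which makes methyl donors, lay higher as a list: 22 of 23 members had positive values (median log2 0.10), 0 passed over all genes and 1 rose when adjusted over the list alone (cth-1). The list had a camera adjusted p of 2.60e-04, and adjusted p = 0.59 with an estimated correlation. Cytosolic ribosomal protein genes lay higher in all 76 members (median 0.13), with 0 past the test over all genes and 0 adjusted over the list alone. Camera gave this ribosomal list adjusted p = 2.89e-05, and adjusted p = 0.978 with an estimated correlation. The 16 members of branched-chain amino acid breakdown had a median of -0.07, with 12 negative, and 0 past the test over all genes and 0 adjusted over the list alone. That list had a camera adjusted p of 0.00799, and adjusted p = 0.978 with an estimated correlation. Propionate breakdown had 11 of 16 members negative (median -0.03, mean -0.18), 0 past the test over all genes, and 1 lower adjusted over the list alone (acdh-2). For propionate breakdown camera gave adjusted p = 0.0317, and adjusted p = 0.978 with an estimated correlation.

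At day 1 edgeR called 0 of 14567 genes, and 297 genes had an unadjusted p under 0.05, against 728 by chance, in a model that pairs no libraries. DESeq2 called 16 and limma-voom 0, and edgeR with no filter called 7. With 2 surrogate variables in the model, added after the data were seen, it called 13. In 1529 genes (10.5%) the groups did not overlap, where chance gives 10%. The count was 1 without bcat-1 day 2 replicate 3, where the gene is bcat-1 itself, and 1 without bcat-1 day 2 replicate 1, where it is C14C6.5. Without bcat-1 day 1 replicate 1 the lists of ribosomal proteins (adjusted p = 0.439), branched-chain breakdown (0.138) and propionate breakdown (0.217) no longer passed, with medians of 0.03, -0.04 and 0.02. Without L4440 day 1 replicate 2 the latter pair did not (0.0683 and 0.112).

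The comparison at day 2 asks the same of worms 1 day older, and here 4 genes of propionate and valine breakdown passed the test, lower on bcat-1 RNAi. None of the 4 passed with only the compared groups in the fit, and neither list passed camera with an estimated correlation (adjusted p = 0.384 for each). hphd-1 (WBGene00012608, chromosome II, 12994354 to 12996571), an oxidoreductase of the propionate shunt, fell from 318 ± 52.6 CPM on L4440 to 130 ± 17.4 CPM (mean ± SD, n = 3 per group; log2 -1.29, SE 0.13, adjusted p = 0.00197). acdh-1 (WBGene00016943, chromosome I, 6497436 to 6499560), the shunt's acyl-CoA dehydrogenase, fell from 791 ± 110 to 459 ± 17.4 CPM (log2 -0.78, SE 0.11, adjusted p = 0.00729). acdh-2 (WBGene00015894, chromosome II, 5544778 to 5547492), of the same enzyme family, fell 8.58-fold from 4.66 ± 2.26 to 0.528 ± 0.187 CPM (log2 -3.1, SE 0.43, adjusted p = 0.00729). hach-1 (WBGene00017301, chromosome III, 5555450 to 5557318), a hydrolase of valine breakdown, fell from 209 ± 30.7 to 116 ± 13.4 CPM (log2 -0.85, SE 0.13, adjusted p = 0.0144). folt-2 (WBGene00018138, chromosome V, 2872465 to 2875600), a folate transporter family gene, fell 4.82-fold from 173 ± 52 to 35.9 ± 6.59 CPM (log2 -2.27, SE 0.20, adjusted p = 0.0018).

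Of the genes with at least 2 CPM and the largest falls at day 2, acs-2, an acyl-CoA synthetase of fatty acid oxidation, went from 54.6 ± 16.6 to 6.37 ± 6.97 CPM (log2 -3.05, adjusted p = 0.0479), and daao-1, a D-amino acid oxidase, fell by 1.96 on the log2 scale. F54E4.2 (-3.02), C09B8.4 (-2.38), F18E3.13 and F18E3.11 (both -1.91), the glucuronosyltransferase gene ugt-53 (-1.60) and C35A5.3 (-1.59) fell too. nhx-6 (WBGene00003734, chromosome II, 1670829 to 1674401), a sodium/proton exchanger gene, rose 13.8-fold from 0.62 ± 0.341 to 8.83 ± 2.67 CPM (log2 3.79, SE 0.39, adjusted p = 0.00197). spp-18 (WBGene00005003, chromosome IV, 9593712 to 9594413), a saposin-like protein gene of the immune effector list, rose 2.89-fold from 13.6 ± 0.756 to 39.4 ± 10.5 CPM (log2 1.53, SE 0.17, adjusted p = 0.00244). asah-1, which encodes an acid ceramidase of the lysosome, rose 2.19-fold from 15.7 ± 2.05 to 34.4 ± 4.08 CPM. The other genes with the largest rises were dod-3 (1.66), F09G8.5 (1.33), F01D5.5 (1.32), F43H9.4 (1.31), the cytochrome P450 gene cyp-14A5 (1.27), F09C8.1 (1.24) and C14C6.5 (1.22).

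**Figure D2:**
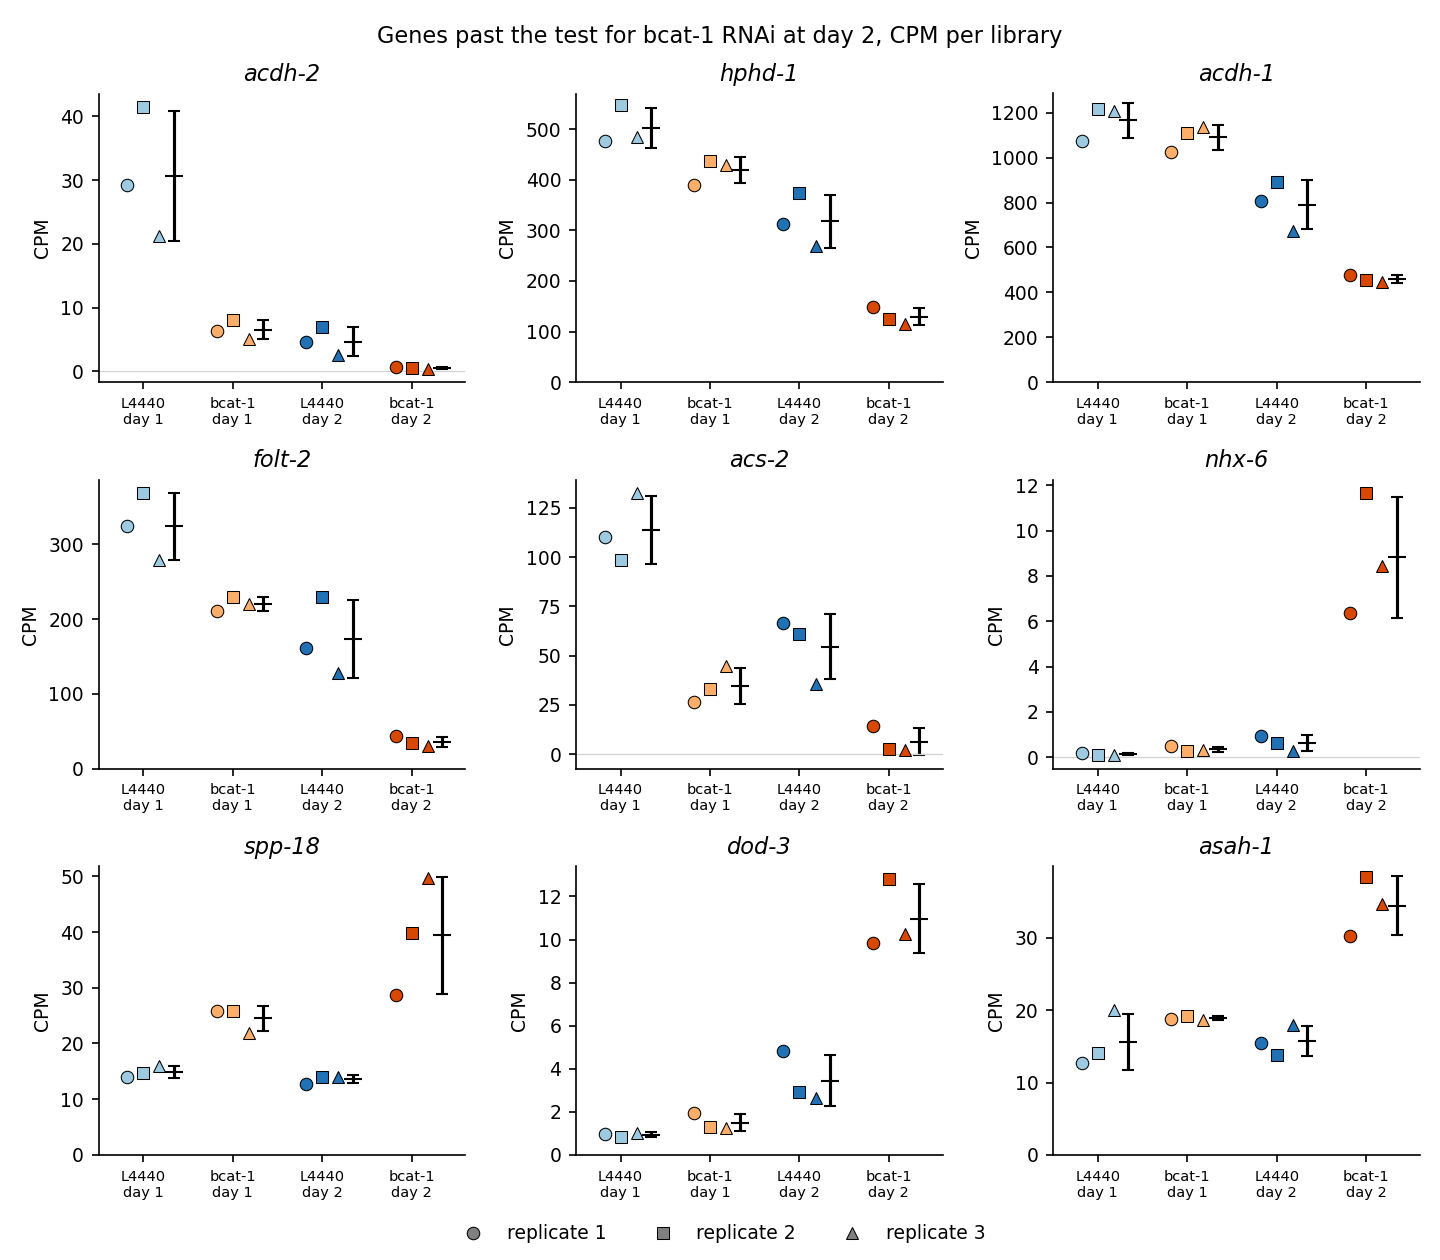
Level (CPM) of 9 genes called at day 2 in each of the 12 libraries, by group; points are libraries and bars are the mean ± SD of 3 libraries. hphd-1 went from 318 to 130 CPM and nhx-6 from 0.62 to 8.83 CPM at day 2.

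At day 2 edgeR called 61 genes, 30 higher and 31 lower on bcat-1 RNAi, 39 of them at least 2-fold. In each the 3 libraries of 1 group lay apart from the 3 of the other, as in 1568 genes (10.8%) of all tested, where chance gives 10%. The count was 15 without bcat-1 day 2 replicate 2, 24 without L4440 day 2 replicate 2, 29 without L4440 day 2 replicate 3, 38 without bcat-1 day 1 replicate 2, and 40 without L4440 day 1 replicate 1 or 2. It was 50 without bcat-1 day 2 replicate 3, the library with high rRNA, 16 higher and 34 lower. Only 40 of these were among the 61, and the others were new calls. With only the compared groups in the fit 599 of 14161 genes had an unadjusted p under 0.05, fewer than chance gives. There edgeR called 0 genes, which ends all 28 named calls. It called 19 with library size only, which keeps 13 of the 28, and 16 against a fold of 1.5, which keeps 13 as well. limma-trend called 5 on log2(RPKM + 1) and 10 on log2(RPKM + 0.1), limma-voom 57 and DESeq2 195. In fits chosen after the data were seen edgeR called 30 without both high-rRNA libraries and 190 with 2 surrogate variables. Of 28 named calls, 11 held with each of the 12 libraries left out (nhx-6, spp-18, cyp-14A5, F09C8.1, C14C6.5, folt-2, daao-1, F18E3.13, ugt-53, C35A5.3 and hphd-1). 17 calls ended without bcat-1 day 2 replicate 2 (acdh-1 at an adjusted p of 0.0587 and acdh-2 at 0.0711), 11 without L4440 day 2 replicate 2 (hach-1 at 0.0713), 9 without L4440 day 2 replicate 3 and 1 to 4 without each of the others. acs-2 lost its call without any of 11 libraries (highest adjusted p 0.183).

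At day 2, 20 of 43 lists passed camera, 3 higher and 17 lower on bcat-1 RNAi, of which 0 held with an estimated correlation and 4 passed fry. 6 of the 20 held with each of the 12 libraries left out, and these are described here. Enzymes of branched-chain amino acid breakdown after the aminotransferase lay lower at day 2 in all 16 members (median log2 -0.26): 1 fell past the test over all genes (hach-1) and 10 fell when adjusted over the list alone. Camera gave it adjusted p = 6.40e-10, adjusted p = 0.384 with an estimated correlation, and fry 0.0412. Propionate breakdown, which shares hach-1, ech-6 and alh-8 with it, had 12 of 16 members negative (median -0.24): hphd-1, acdh-1, acdh-2 and hach-1 fell over all genes and 6 fell adjusted over the list alone. Its camera adjusted p was 1.58e-06, and adjusted p = 0.384 with an estimated correlation. TCA and glyoxylate cycle genes were negative in 28 of 28 members (median -0.21), with 0 past the test over all genes, and 2 lower adjusted over the list alone. The TCA list had a camera adjusted p of 3.02e-08, and adjusted p = 0.394 with an estimated correlation. Glycolysis and gluconeogenesis genes were negative in 21 of 22 members (median -0.17), with 0 past the test over all genes, and 1 lower adjusted over the list alone. The glycolysis list had a camera adjusted p of 3.52e-05, and adjusted p = 0.384 with an estimated correlation. Vacuolar ATPase genes, which acidify lysosomes, were negative in 18 of 20 members (median -0.23), with 0 past the test over all genes, and 0 adjusted over the list alone. The ATPase list had a camera adjusted p of 4.39e-06, and adjusted p = 0.384 with an estimated correlation. Histone genes are near-identical copies whose reads cannot be placed with certainty and whose transcripts mostly lack poly(A) tails. They were positive in 23 of 25 members (median 0.40), with 0 past the test over all genes and 8 higher adjusted over the list alone. Camera gave the histone list adjusted p = 1.58e-07, and adjusted p = 0.394 with an estimated correlation. Their highest level relative to the other 11 libraries was in bcat-1 day 2 replicate 3 (median deviation 0.50 log2), the library with 41.46% rRNA. That library also had the lowest mean of the TCA list among the day 2 libraries (score -0.46, against -0.135 and -0.126 in bcat-1 replicates 1 and 2). The same held for branched-chain breakdown (-0.541, against -0.321 and -0.245) and propionate breakdown (-0.685, against -0.403 and -0.467). It held for glycolysis (-0.275, against -0.103 and -0.149) and vacuolar ATPase (-0.328, against -0.148 and -0.166) in that library too. Without it the day 2 medians were -0.13 for the TCA list, -0.11 for propionate breakdown, -0.15 for vacuolar ATPase and 0.22 for histones. They were -0.20 for branched-chain breakdown and -0.16 for glycolysis. Markers of tissues and germline passed camera at day 2 beside these lists, all lower and each with 0 genes past the test over all genes. Their medians were -0.41 for collagens (camera adjusted p = 0.00553), -0.17 for muscle markers (0.00303) and -0.15 for epidermis markers (0.047). Oocyte and maternal genes had -0.12 (0.00811) and germline proliferation and meiosis genes -0.13 (8.86e-04). With an estimated correlation their adjusted p ran from 0.729 to 0.801. Collagens, muscle and epidermis markers did not pass without bcat-1 day 2 replicate 2 (0.605, 0.536 and 0.596). The oocyte and germline lists did not pass without L4440 day 2 replicate 2 (0.662 and 0.488). Without L4440 day 2 replicate 1 the medians of muscle and epidermis markers turned to 0.03 and 0.07. Replicate 1 had the highest day 2 score of its food on both lists. The muscle scores were 0.374 on L4440 and 0.134 on bcat-1 RNAi, and the epidermis scores 0.662 and 0.45. Leaving out only the L4440 library therefore also makes the foods less alike in this respect. Intestine, neuron, and somatic gonad and vulva markers did not pass at day 2 (camera adjusted p 0.589, 0.799 and 0.681).

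**Figure D3:**
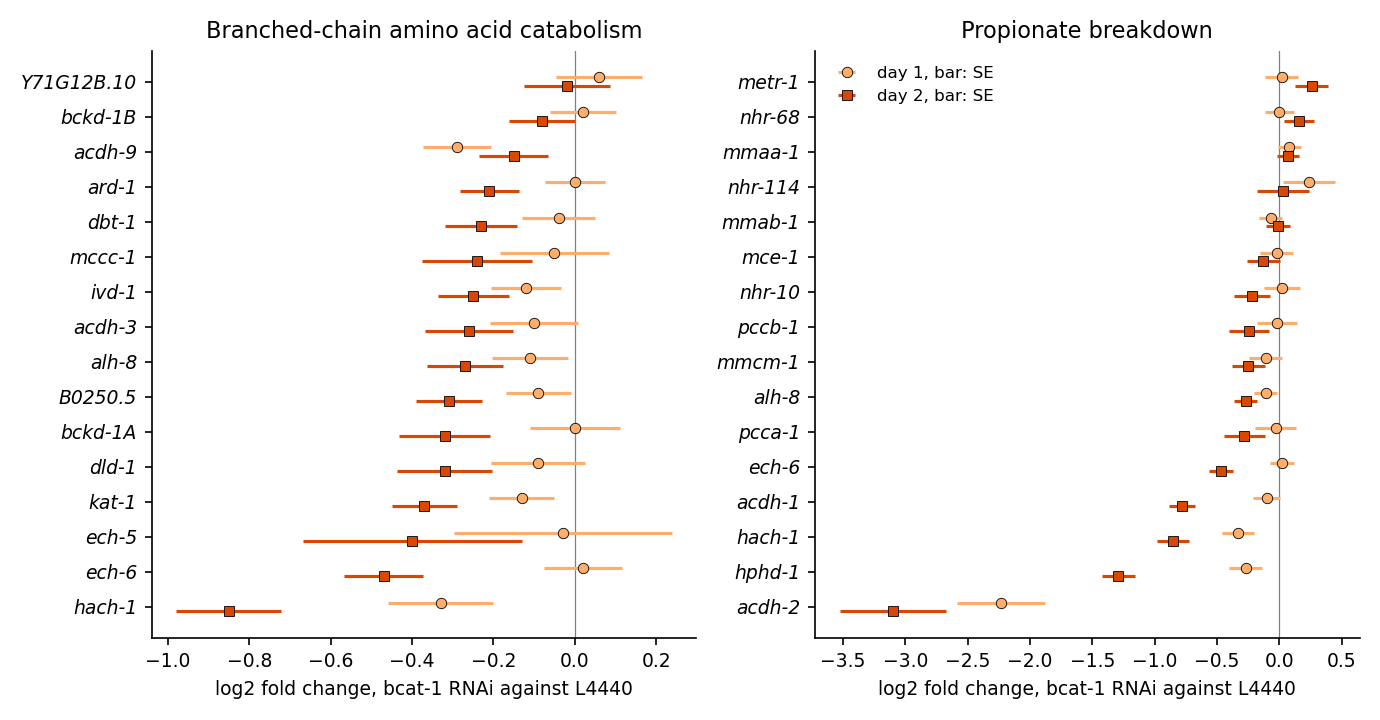
log2 fold change (bcat-1 RNAi over L4440) of each tested member of branched-chain amino acid breakdown and propionate breakdown at day 1 and day 2; points are fitted values and bars are ± SE. At day 2 all 16 members of the first list and 12 of 16 of the second are negative, under TMM factors and under library size only alike for the list medians.

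Among detoxification and defence genes at day 2, the immune effector list had 2 genes that rose, spp-18 and the lysozyme gene lys-4 (log2 0.76, adjusted p = 0.0262), and 6 rose and 1 fell adjusted over the list alone. The immune list as a whole did not pass (camera adjusted p = 0.0651, adjusted p = 0.729 with an estimated correlation), and its median of 0.07 turned to -0.07 under library size only. That scaling moved the median of all genes as well, from -0.017 to -0.136, so the turn is not particular to the list. Of 59 glucuronosyltransferase genes ugt-53, ugt-6 (-1.4) and ugt-46 (-0.62) fell, and 1 rose and 4 fell adjusted over the list alone. That list did not pass (camera adjusted p = 0.0927), and its median of -0.02 turned to 0.02 under upper-quartile factors, as the median of all genes did (-0.017 to 0.019). Of 61 cytochrome P450 genes cyp-14A5 rose and cyp-34A8 (-1.02) fell, with 2 higher and 2 lower adjusted over the list alone. Of 39 lipolysis and beta-oxidation genes hacd-1 (0.83), a hydroxyacyl-CoA dehydrogenase, rose and acs-2 fell, with 4 higher and 5 lower adjusted over the list alone. Camera gave the lipolysis list adjusted p = 0.0493 (median -0.11), adjusted p = 0.729 with an estimated correlation, and up to 0.372 in 9 of the 12 fits without 1 library. Of those genes lys-4 lost its call without any of 6 libraries (highest adjusted p 0.122), hacd-1 of 4 (0.147), ugt-6 of 3 (0.0847) and ugt-46 of 11 (0.187). cyp-34A8 lost it without bcat-1 day 2 replicate 2 (0.057).

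The difference between the effects at day 2 and day 1 was tested for every gene, and 0 passed edgeR's test. In this test 385 genes had an unadjusted p under 0.05, against 728 by chance. DESeq2 called 13 and limma-voom 0. The genes with the smallest p, chosen after their values were seen, were folt-2 (difference -1.71, SE 0.27), ugt-6 (-1.61, SE 0.29) and hphd-1 (-1.03, SE 0.18), each with adjusted p = 0.351. Of the 61 genes called at day 2, 55 (90.2%) had the same sign at day 1, against 61.4% of all genes, and in 60 the day 1 value was smaller (median ratio 0.32). Genes picked for a large value on 1 day are smaller on another by selection alone. No gene was called at both days. Across 14567 genes, which are not independent replicates, the effects of the days had a Pearson r of 0.169 and a Spearman rho of 0.218. As lists, 17 of 43 differed between days by camera, 3 higher and 14 lower at day 2, of which 0 held with an estimated correlation and 0 by fry.

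**Figure D4:**
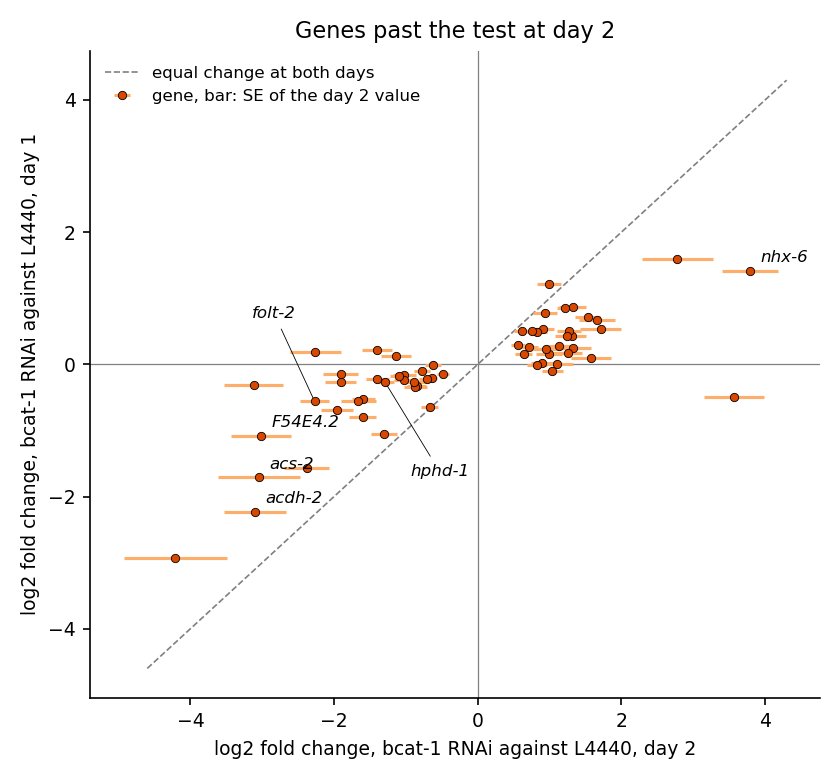
log2 fold change under bcat-1 RNAi at day 1 (vertical) against day 2 (horizontal) for the 61 genes called at day 2; bars are ± SE at day 2 and the dashed line marks equal change. 55 genes have the same sign at both days, and 60 are smaller at day 1.

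The comparison of day 2 with day 1 on L4440 describes the change with age in control worms. sri-40, a chemoreceptor family gene, fell from 27.9 ± 3.51 to 3.38 ± 0.295 CPM (mean ± SD, n = 3 per group; log2 -3.05, SE 0.18, adjusted p = 2.14e-05). acdh-2 fell from 30.7 ± 10.2 to 4.66 ± 2.26 CPM (-2.71, SE 0.36, adjusted p = 0.00362), and acox-1.3, a peroxisomal acyl-CoA oxidase gene, fell by 2.18 on the log2 scale. T22B7.7 rose 18.1-fold from 6.76 ± 2.61 CPM (4.18, SE 0.41, adjusted p = 6.28e-04) and pud-4 rose by 2.51. The other genes with the largest changes were hhat-1 (4.00), F40E10.5 (3.46), Y41D4B.6 (2.94) and dsl-6 (2.87), which rose, and the collagen genes col-93 (-2.33) and col-129 (-1.86) and F55H12.2 (-1.88), which fell.

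By list on L4440, 10 of 47 immune effectors rose from day 1 to day 2 and 1 fell (lys-4, -0.66), with K08D8.5 (1.42), the lysozyme gene lys-2 (1.07) and the C-type lectin gene clec-85 (0.96) as examples. Of the list 21 rose and 1 fell adjusted over the list alone, with camera adjusted p = 4.94e-05 and adjusted p = 0.441 with an estimated correlation. Of 18 genes of the DAF-16 class II list, lowered when the FOXO factor DAF-16 is active, 6 rose (dct-17 1.64, pud-3 2.37 and dod-24 1.65 among them), and 13 rose and 1 fell adjusted over the list alone. For DAF-16 class II camera gave adjusted p = 3.07e-06, and adjusted p = 0.441 with an estimated correlation. Genes of the DAF-16 class I list, known to be raised by DAF-16, had a positive median on L4440 too (0.33). The medians of both lists were thus higher at day 2, which gives no direction for DAF-16 activity. Branched-chain amino acid breakdown was negative in all 16 members (median -0.20): 5 fell (acdh-9 -1.29, ech-6 -0.58, alh-8 -0.50 and hach-1 -0.64 among them) and 8 fell adjusted over the list alone. The branched-chain list had a camera adjusted p of 8.66e-07, and adjusted p = 0.441 with an estimated correlation. Propionate breakdown had 6 genes that fell, acdh-1 (-0.56) among them, and 8 adjusted over the list alone (median -0.29, camera adjusted p = 1.80e-05, adjusted p = 0.441 with an estimated correlation). Of 29 genes switched on in embryos, which hermaphrodites hold in the uterus, 4 fell (ceh-51 -1.84, end-1 -2.29, hnd-1 -0.95 and sdz-1 -1.69) and 2 rose, with 8 lower and 2 higher adjusted over the list alone. The embryo list had a camera adjusted p of 3.82e-04, and adjusted p = 0.441 with an estimated correlation; its median of -0.24 was -0.10 without L4440 day 2 replicate 2. Moulting and larval timing genes had a median of 0.69, yet only grd-5 passed over all genes and it fell (-0.72), while 12 rose and 3 fell adjusted over the list alone. Camera gave the moulting list adjusted p = 0.00251, adjusted p = 0.793 with an estimated correlation, and 0.0799 (median 0.32) without L4440 day 2 replicate 1. Neuron markers had a median of 0.38, with 1 gene that rose (osm-6, 1.05) over all genes and 1 adjusted over the list alone. Camera gave the neuron list adjusted p = 0.00346, adjusted p = 0.81 with an estimated correlation, and 0.412 (median 0.12) without L4440 day 2 replicate 1. That library had the highest moulting score of all 12.

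On L4440 edgeR called 335 genes between days, 147 higher and 188 lower at day 2, 172 of them at least 2-fold. Over all genes 3605 (24.7%) had groups that did not overlap, where chance gives 10%. The count was 79 without L4440 day 1 replicate 2, 45 higher and 81 lower genes without L4440 day 1 replicate 1, and 50 higher and 73 lower without L4440 day 1 replicate 3. It was 206 and 196 without bcat-1 day 1 replicates 2 and 3, and 166 and 118 without L4440 day 2 replicates 1 and 3. It was 1017, 729 and 574 without L4440 day 2 replicate 2, bcat-1 day 2 replicate 1 and bcat-1 day 2 replicate 3. Of 61 named calls 24 held with each library left out, sri-40, acdh-2, acox-1.3, T22B7.7, pud-4, col-129, acdh-9, dct-17, pud-3, K08D8.5, lys-2, clec-85, ceh-51, end-1 and hnd-1 among them. 36 calls ended without L4440 day 1 replicate 2, 32 without L4440 day 2 replicate 3, 29 and 23 without L4440 day 1 replicates 3 and 1, and 25 without L4440 day 2 replicate 1. Another 18, 16 and 7 ended without bcat-1 day 1 replicates 3, 2 and 1, and 2 and 3 without L4440 and bcat-1 day 2 replicate 2.

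On bcat-1 RNAi the comparison of day 2 with day 1 shared acdh-2, sri-40, T22B7.7, pud-4, col-93 and col-129 with L4440 among its largest changes. nhx-6 rose from 0.36 ± 0.114 to 8.83 ± 2.67 CPM (n = 3 per group; log2 4.59, SE 0.42, adjusted p = 1.14e-04), and pud-4 (4.28), pud-3 (3.86), T22B7.7 (3.28), B0024.4 (2.92) and dod-3 (2.88) rose. acdh-2 fell by 3.58 on the log2 scale (SE 0.43, adjusted p = 8.81e-04) and folt-2 fell from 220 ± 8.87 to 35.9 ± 6.59 CPM (-2.61, SE 0.21, adjusted p = 8.72e-05). sri-40 (-2.66) and the collagen genes col-93 (-2.64), col-133 (-2.53) and col-129 (-2.46) fell too.

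By list on bcat-1 RNAi, branched-chain amino acid breakdown was negative in all 16 members (median -0.44): 10 fell (acdh-9 -1.15, ech-6 -1.07, hach-1 -1.16 and kat-1 -0.64 among them) and 12 fell adjusted over the list alone. Camera gave it adjusted p = 7.51e-13, and adjusted p = 0.0902 with an estimated correlation. Propionate breakdown had 7 genes that fell over all genes and 7 adjusted over the list alone, hphd-1 (-1.69) and acdh-1 (-1.25) with the smallest adjusted p. Its median was -0.18 (-0.28 without bcat-1 day 2 replicate 2), with camera adjusted p = 1.15e-08 and adjusted p = 0.0902 with an estimated correlation. Nuclear genes of the respiratory chain were negative in 51 of 51 members (median -0.23), with 3 that fell over all genes and 24 adjusted over the list alone. The respiratory list had a camera adjusted p of 1.64e-11, and adjusted p = 0.0902 with an estimated correlation. Vacuolar ATPase genes had 7 that fell over all genes and 16 adjusted over the list alone (median -0.33, camera adjusted p = 3.79e-09, adjusted p = 0.0902 with an estimated correlation). Of 47 immune effectors 16 rose and 1 fell over all genes, and 25 rose and 2 fell adjusted over the list alone, with lys-1 (0.77), thn-2 (1.26), lys-2 (1.05) and cnc-4 (2.66) as examples. Camera gave the effectors adjusted p = 1.29e-07, and adjusted p = 0.0902 with an estimated correlation. Of the collagens 25 fell over all genes, and 11 rose and 31 fell adjusted over the list alone. Their median was 0.33 while the camera direction was down (adjusted p = 0.184, not past the test).

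On bcat-1 RNAi edgeR called 593 genes between days, 293 higher and 300 lower at day 2, 266 of them at least 2-fold. Over all genes 3067 (21.1%) had groups that did not overlap, where chance gives 10%. Of 222 genes called on both foods in 1 direction 96 were higher at day 2, where 2.96 would be if calls were independent (one-sided Fisher's exact p = 2.39e-131), and the rest were lower, against 3.87 (one-sided Fisher's exact p = 3.65e-176). 0 genes were called in opposite directions. Fisher's test takes genes as independent, which they are not, and both comparisons take the spread of a gene from 1 fit. These p-values therefore do not measure how well the change with age repeats. The count of genes called between days on bcat-1 RNAi was 347, 229 and 261 without bcat-1 day 1 replicates 1, 2 and 3. Of 93 named calls 50 held with each library left out, the genes described for this comparison among them except col-93 (adjusted p = 0.0667 without bcat-1 day 1 replicate 2) and col-133 (highest 0.136, lost without any of 7 libraries). 39, 33 and 21 calls ended without bcat-1 day 1 replicates 2, 3 and 1, 19, 18 and 8 without bcat-1 day 2 replicates 1, 2 and 3, and 2 to 12 without each L4440 library.

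The day 2 libraries differed among themselves in cuticle and moult transcripts. The moulting score, the mean log2 CPM of the list with gene means subtracted, was 1.16, -0.24 and 0.59 in L4440 day 2 replicates 1, 2 and 3 and 1.06, -0.17 and -0.01 in bcat-1 day 2 replicates 1, 2 and 3. Replicate 1 of each food also stood apart on the first principal component, which held 54.6% of the variance, at 71.8 and 61.9 against -45.1 to 40.1 in the other 10 libraries. bcat-1 day 2 replicate 3, the library with 41.46% rRNA, stood apart on the second component (14.1% of the variance) at -58.1, against -13.9 to 20.4 in the other 11. The genes at the ends of that component include rrn-3.1, nhx-6 and dod-3 on its side and acs-2, acdh-2 and folt-2 on the other. Mitochondrial-genome protein genes, a further sign of RNA composition, had a median of 0.09 under bcat-1 RNAi at day 2 in 12 genes, with 0 past the test. It turned negative under library size only, where the median of all genes also moved, from -0.017 to -0.136. Their score was 0.323 in bcat-1 day 2 replicate 3 and -0.093 and -0.104 in replicates 1 and 2, against -0.075 to -0.037 in the L4440 day 2 libraries. Without replicate 3 the median was 0.01.

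**Figure D5:**
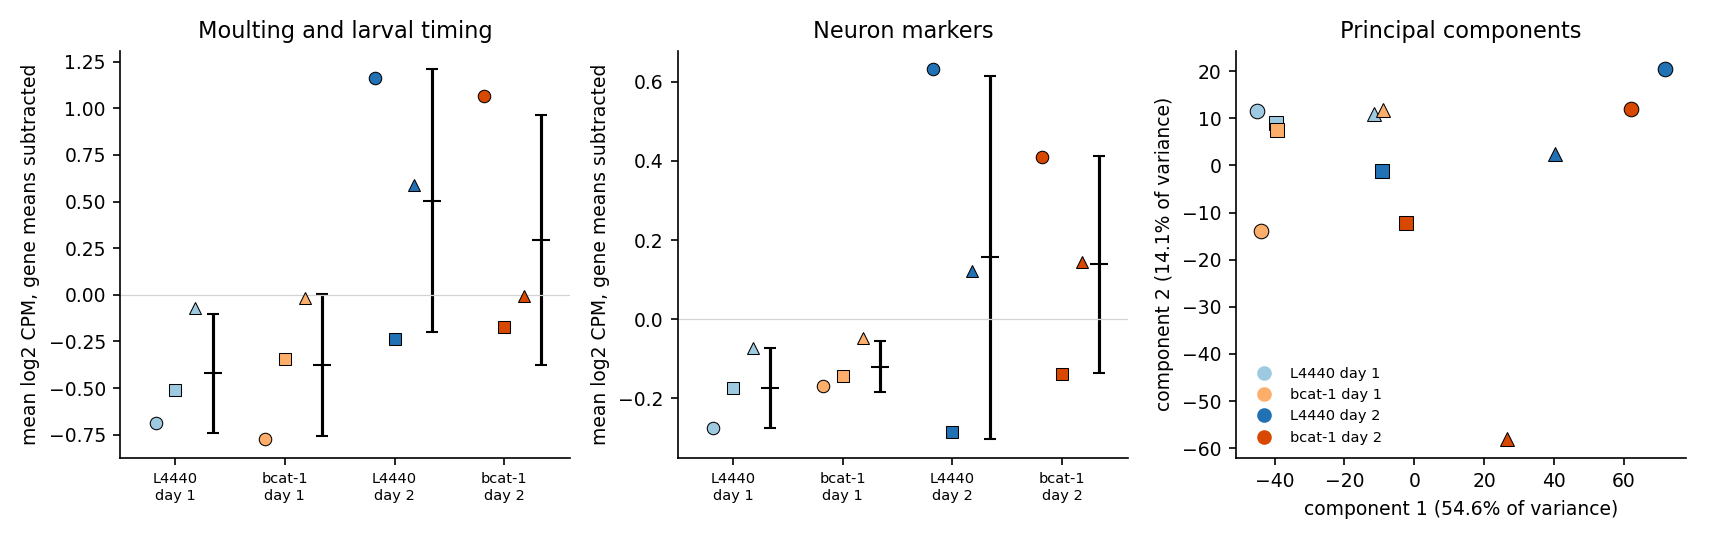
Moulting and neuron marker scores (mean log2 CPM with gene means subtracted) of each library by group, with bars for the mean ± SD of 3 libraries, and the first and second principal components of log2 CPM (54.6% and 14.1% of variance). The moulting score is 1.16 and 1.06 in replicate 1 of the day 2 groups and -0.24 and -0.17 in replicate 2.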

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

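The tests of a wrong label, of RNAi that did not take, of rRNA carry-over and of late embryos or larvae were chosen only after the result was seen. Lists of genes stand here because the effect of bcat-1 RNAi differed between day 1 and day 2 in a test of the difference itself (camera, over 43 lists), and none of the 17 calls held with an estimated correlation.

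9 lists of metabolic and organelle genes had lower effects at day 2 than at day 1. The difference for vacuolar ATPase genes had a median of -0.20 log2 and an adjusted p of 1.99e-07 (adjusted p = 0.317 with an estimated correlation). TCA and glyoxylate cycle genes had -0.19 and 6.06e-06 (0.538 with an estimated correlation), branched-chain amino acid breakdown -0.21 and 1.3e-05 (0.538), and propionate breakdown -0.21 and 0.000144 (0.538). Glycolysis and gluconeogenesis had -0.15 and 0.000156 (0.317), hypoxia and hydrogen sulfide response genes, hphd-1 among them, -0.28 and 0.000259 (0.317), and other amino acid breakdown -0.15 and 0.000717 (0.538). Nuclear genes of the respiratory chain had -0.10 and 0.000156 (0.538), with an adjusted p of 0.152 without bcat-1 day 2 replicate 1. Proteasome genes had -0.12 and 0.000479 (0.863), with 0.289 without bcat-1 day 2 replicate 1 and 0.252 without L4440 day 2 replicate 2. 3 lists had higher effects at day 2. The intracellular pathogen response had 0.37 and 0.000452 (0.41 with an estimated correlation). Histones had 0.30 and 0.000156 (0.539), with 0.235 without bcat-1 day 2 replicate 3. Neuropeptides had 0.10, which turned to -0.05 under library size only and to -0.09 without bcat-1 day 2 replicate 3, and 0.00119 (0.878), with 0.108 without L4440 day 2 replicate 2 and 0.161 without bcat-1 day 2 replicate 3. Library size only moved the median of all genes as well, from -0.033 to -0.131.

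5 lists of tissue and germline markers had lower effects at day 2 too, in libraries that differed in their moulting score. Intestine, neuron, and somatic gonad and vulva markers did not pass (adjusted p = 0.67, 0.605 and 0.527). Collagens had a median difference of -0.51 and an adjusted p of 8.5e-05 (0.863 with an estimated correlation), with 0.622 without bcat-1 day 2 replicate 2. Muscle markers had -0.22 and 0.000259 (0.863), with 0.202 without L4440 day 2 replicate 1 and 0.175 without bcat-1 day 2 replicate 2. Epidermis markers had -0.23 (0.01 without L4440 day 2 replicate 1) and 0.0323 (0.863), with 0.0626, 0.0505, 0.201, 0.288, 0.469 and 0.0991 without L4440 day 1 replicate 2, bcat-1 day 1 replicate 2, bcat-1 day 1 replicate 3, L4440 day 2 replicate 1, bcat-1 day 2 replicate 2 and L4440 day 2 replicate 3. Oocyte and maternal genes had -0.13 and 0.00457 (0.863), with 0.0903, 0.459 and 0.562 without bcat-1 day 1 replicate 1, bcat-1 day 2 replicate 1 and L4440 day 2 replicate 2. Germline proliferation and meiosis genes had -0.10 and 0.0379 (0.878), with 0.0936, 0.0846, 0.411 and 0.529 without bcat-1 day 1 replicates 1 and 2 and bcat-1 day 2 replicates 1 and 3, and 0.0704, 0.266, 0.868 and 0.0784 without L4440 day 1 replicates 2 and 3 and L4440 day 2 replicates 2 and 3.

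The bcat-1 transcript stood at 329 CPM in the library labelled bcat-1 day 2 replicate 3, above every L4440 library. An L4440 sample under a wrong label needs this library to sit with L4440 on the other genes that differ between the foods. RNAi that did not take in these worms needs this only for genes that answer to the knockdown itself. Its position was taken over 49 genes called at day 2 without this library. The scale ran from 0 at the L4440 mean to 1 at the mean of the other bcat-1 libraries. The median position was 1.02 (quartiles 0.75 and 1.21), and 42 genes (85.7%) lay on the bcat-1 side of 0.5, which argues against a wrong label. RNAi that did not take cannot be decided this way, because whether these genes answer to the knockdown or to the bacteria was not tested. RNA without poly(A) tails carried into the library, the fed double-stranded RNA included, may be the source and stays open: the library had 41.46% rRNA and its histones stood 0.50 above the other libraries (highest other 0.27), but 32 snRNA and snoRNA genes stood only 0.17 above them, under the 0.28 of bcat-1 day 1 replicate 1, which had 0.20% rRNA and 19.5 CPM of bcat-1. The bound set for that test was another library with a higher value, and it is not decisive because 0.17 and 0.28 differ by less than the SD of 0.14 between the other libraries, so these cannot be told apart.

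Cuticle and moult transcripts were high in part of the day 2 libraries, on both foods. Carry-over of rRNA does not go with the moulting genes: Spearman's rho of the moulting score and the rRNA share was -0.26 over the 6 day 2 libraries (exact permutation p = 0.658, adjusted 0.658; Pearson r -0.30, exact permutation p = 0.742, adjusted 0.816, and 0.07 without the 2 farthest), and L4440 and bcat-1 replicate 1 with 0.08% and 0.20% rRNA scored 1.16 and 1.06 where replicate 2 with 0.11% and 0.22% scored -0.24 and -0.17. For collagens it stays open: their score and the rRNA share had a rho of 0.43 over the same libraries (exact permutation p = 0.419; Pearson r 0.50, exact permutation p = 0.294). Their highest scores were in the libraries with 6.74% and 41.46% rRNA (0.892 and 0.855), yet L4440 replicates 1 and 2, with 0.08% and 0.11%, lay at 0.707 and -0.493. 6 libraries are too few to tell these apart. Late embryos or larvae in the samples are a candidate explanation, as neuron markers rose with the moulting score (Pearson r 0.92, exact permutation p = 0.00556, adjusted 0.0306 over 11 relations, 0.72 without the 2 farthest; rho 0.94, p = 0.0167, adjusted 0.0918), and so did muscle markers (r 0.96, exact permutation p = 0.00278, adjusted 0.0306, 0.93 without the 2 farthest; rho 0.94, p = 0.0167, adjusted 0.0918). Not every list goes with it: neuropeptides, which are neuronal too, had r 0.15 (exact permutation p = 0.819, adjusted 0.819, 0.11 without the 2 farthest; rho 0.66, p = 0.175, adjusted 0.275), and somatic gonad and vulva markers rose as well (r 0.93, exact permutation p = 0.0181, adjusted 0.0664, 0.63 without the 2 farthest; rho 0.83, p = 0.0583, adjusted 0.16). Zygotic embryo genes had r 0.86 (exact permutation p = 0.0472, adjusted 0.0942) but 0.30 without the 2 farthest. Epidermis markers had r 0.83 (exact permutation p = 0.0472, adjusted 0.0942, 0.88 without the 2 farthest). Intestine markers had r 0.82 (exact permutation p = 0.0514, adjusted 0.0942, -0.25 without the 2 farthest). The rise was thus not particular to neuron and muscle markers. A lower share of germline stays open as well, with r -0.44 for germline genes (exact permutation p = 0.367, adjusted 0.449; rho -0.60, p = 0.242, adjusted 0.296; -0.15 without the 2 farthest), as does age within day 2, which was not tested. Each food has 3 day 2 libraries, too few for the relation within a food. The exact permutation p-values take the 6 libraries as exchangeable. Yet replicate 1 of both foods lay close together after group means were removed (r across genes 0.72), and so did replicate 2 (0.73). The permutation p-values may therefore be too small.

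The day 2 effect of bcat-1 RNAi was compared with the change from day 1 to day 2 on L4440, which shares the L4440 day 2 libraries. Of the 61 genes called at day 2, 36 had the sign of that change, 23 of 31 lower and 13 of 30 higher ones, and 15 of the 18 that were also called between days had its direction. No value to expect without a relation was computed for these counts. Over the 335 genes called between days 45.4% had the same sign, and over all genes r was -0.347 (mean -0.499 in simulations with no effect), and the shared libraries push both down. If worms on bcat-1 RNAi were further along the whole change, the RNAi effect would be a like share of it in every gene, but its median ratio to the change was -0.04 over the 335 genes called on L4440 (quartiles -0.28 and 0.23). That bound is not decisive, because the L4440 day 2 libraries enter both values with opposite signs and push the ratio down. Another ratio was taken to the change on bcat-1 RNAi, over the 593 genes called there, and its median was 0.30. The bcat-1 day 2 libraries enter both values of that ratio with the same sign and push it up. Chance covariance from the shared libraries needs a covariance over genes within the range of simulations with no effect, and a value above that range would go against it. It was -0.082, below all 20 simulations (mean -0.058, -0.063 to -0.054), so it meets neither bound, and the simulations hold no structure shared between genes. These cannot be told apart with the same L4440 day 2 libraries in both comparisons, so a shift in age may or may not underlie part of the day 2 effect.

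Other splits of the same 6 libraries give a count for each comparison of 3 against 3, and 10 splits are too few for a share under 0.05. At day 1 the real split called 0 genes and the highest other 0, so all 10 splits call as many by construction and the count decides nothing. At day 2 the real split called 61, and 2 of 10 splits, the real one included, called as many: the highest other called 1314, with L4440 replicates 1 and 3 and bcat-1 replicate 1 against the rest. These are the 3 libraries with the highest moulting scores, so that split points to a structure of the samples other than food. For the difference between days the real split called 0, so all 100 drawn splits call as many by construction and this count decides nothing either. The highest drawn split called 993, which points to a structure of the samples, and its kind was not tested. Between days the real split called 335 on L4440 and 593 on bcat-1 RNAi, 1 of 10 splits each, with 0 in the highest other.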

How the results depend on the processing

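Leaving out rRNA genes, leaving out both libraries with over 5% rRNA and adding surrogate variables were tests chosen after the data were seen. No paired analysis was possible from the labels, because they give no replicate numbers. A fit that pairs libraries by sample order could have been made and was not run, since it would rest on no label. No named gene that was called reversed its direction in any setting run. The camera direction of called lists reversed, with no call, for collagens at day 2 without bcat-1 day 2 replicate 2 (adjusted p = 0.605), for germline genes in the difference between days without L4440 day 2 replicate 2 (0.868), and for neuropeptides without bcat-1 day 2 replicate 3 (0.73 at day 2, 0.161 for the difference) or without both high-rRNA libraries (0.724 and 0.17). With 2 surrogate variables it reversed for germline genes (0.411) and neuron markers (0.962) between days on bcat-1 RNAi. Over all fits without 1 library these lists ran from 2.47e-18 to 0.605 (collagens), 1.83e-05 to 0.868 (germline), 7.60e-09 to 0.73 and 2.64e-07 to 0.161 (neuropeptides at day 2 and for the difference). The median of neuropeptides for the difference turned from 0.10 to -0.05 under library size only, with the camera direction kept. The bcat-1 value at day 2, which did not pass, changed sign without bcat-1 day 2 replicate 1 or 2. The p-values rest on 3 libraries per group. On simulated data edgeR recovered 74.6% of 2-fold changes at day 1, 73.1% at day 2 and 37.3% for the difference between days, so smaller changes can be missed. DESeq2 made 17.7% false calls at day 2 against 2.7% for edgeR. The edgeR share was 7.1% at day 1, 2.2% for the difference, and 5.4% and 5.9% between days on L4440 and bcat-1 RNAi. Simulated counts came from edgeR's own dispersions with no structure shared between genes. They therefore neither rank DESeq2 against edgeR nor give the recovery in the real libraries. The median of all genes shifted under some scalings: with library size only it was -0.136 at day 2 (-0.017 with TMM), -0.131 for the difference between days (-0.033) and -0.106 between days on bcat-1 RNAi (-0.005); with log2(RPKM + 1) it was -0.12 at day 1 and -0.115 between days on L4440, and with log2(RPKM + 0.1) -0.166 at day 1, -0.113 at day 2 and -0.15 between days on L4440. The RPKM values are not scaled to their own library. The cause was not tested for the values that follow, unless stated.

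Genes called by bcat-1 RNAi at day 1 numbered 0 and became 16 with DESeq2, 7 with no filter, 2 with log2(RPKM + 0.1), 1 with only the compared groups (bcat-1), 1 with both high-rRNA libraries out (bcat-1), 1 with 1 surrogate variable (C14C6.5) and 13 with 2. They ranged from 0 to 1 with 1 library left out, 1 being bcat-1 without bcat-1 day 2 replicate 3 and C14C6.5 without bcat-1 day 2 replicate 1. The 61 at day 2 became 19 with library size only, 195 with DESeq2 (59 of the 61 among them), 16 against a fold of 1.5, which by construction calls fewer, 5 with log2(RPKM + 1), 10 with log2(RPKM + 0.1), 0 with only the compared groups (edgeR, 599 at an unadjusted p under 0.05), 30 with both high-rRNA libraries out (27 shared) and 190 with 2 surrogate variables (all 61 among them), and from 15 (bcat-1 day 2 replicate 2) to 81 (bcat-1 day 2 replicate 1) with 1 library out. They were 51 to 87 with RLE and upper-quartile factors, limma-voom, no filter, the stricter filter, no rRNA genes or 1 surrogate variable. The difference between days went from 0 to 13 with DESeq2 and 1 with no filter (folt-2), and ranged from 0 to 0 with 1 library out. The overlap of the days went from 0 to 14 with DESeq2, 5 with no filter, 1 with both high-rRNA libraries out, 1 with 1 surrogate variable and 10 with 2, and from 0 to 1 with 1 library out.

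The 335 genes between days on L4440 became 100 with library size only, 999 with DESeq2, 867 with no filter, 35 against a fold of 1.5, 5 with log2(RPKM + 1), 185 with log2(RPKM + 0.1), 764 and 1881 with 1 and 2 surrogate variables, and from 79 (L4440 day 1 replicate 2) to 1017 (L4440 day 2 replicate 2) with 1 library out. The 593 on bcat-1 RNAi became 244 with library size only, 1021 with DESeq2, 87 against a fold of 1.5, 25 with log2(RPKM + 1), 128 with log2(RPKM + 0.1), 222 with only the compared groups, 1362 and 2258 with 1 and 2 surrogate variables, and from 229 (bcat-1 day 1 replicate 2) to 657 (L4440 day 2 replicate 1) with 1 library out.

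In the planned fit of only the compared groups, bcat-1 was the 1 gene called at day 1. The bcat-1 log2 value of -2.98 at day 1 also passed the test at -3.0 with both high-rRNA libraries out and at -3.51 with 2 surrogate variables, and ranged from -3.21 to -2.87 with 1 library out. At day 2 it went from -0.21 to -3.26 and -2.91 in those settings, and from -3.15 (bcat-1 day 2 replicate 3) to 0.32 (bcat-1 day 2 replicate 1) with 1 library out. Leaving out the library with 329 CPM removes the value that held the mean up.

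Lists called at day 1 went from 4 to 0 with an estimated correlation, 0 with fry, 9 with both high-rRNA libraries out and 2 with 1 surrogate variable, and from 2 (L4440 day 1 replicate 2) to 10 (L4440 day 1 replicate 3) with 1 library out. At day 2 the 20 became 0 with an estimated correlation and 4 with fry (16 to 20 with 1 library out). For the difference between days the 17 became 0 and 0 (15 to 22). Between days on L4440 the 19 became 0 and 8 (12 to 20, the lowest without L4440 day 2 replicate 1). Between days on bcat-1 RNAi the 22 became 0 with an estimated correlation and 15 with fry (20 to 26 with 1 library out). Of the values of named genes with 1 library out, 272 of 336 at day 2, 541 of 732 on L4440 and 938 of 1116 on bcat-1 RNAi kept their direction and their call, and the others kept their direction only. In the other settings 297 of 420, 686 of 913 and 1042 of 1390 did.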

Other observations

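All tests of this part were planned before the data were examined, except the comparison of residuals between libraries, which was chosen after the result was seen.

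More gene groups were compared between days, and not all passed as lists. On L4440 the intestinal protease gene cpr-5 (-1.44), the aquaporin gene aqp-8 (-1.11) and the protease gene asp-1 (-0.72) fell from day 1 to day 2; of 31 intestine markers 1 rose and 5 fell over all genes, and 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.017, adjusted p = 0.481 with an estimated correlation; 0.054 without L4440 day 2 replicate 2). The adult collagen gene col-19 (-1.13) and col-20 (-1.70) fell as well; among collagens 2 rose and 12 fell over all genes, and 19 rose and 15 fell adjusted over the list alone, while their median was 0.75 and the list did not pass (0.57). On bcat-1 RNAi the troponin gene tnt-2 (-1.11) and the calponin-like gene unc-87 (-0.73) fell; of 35 muscle markers 7 fell over all genes and 13 adjusted over the list alone (median -0.36, from -0.58 to -0.20 with 1 library left out, camera adjusted p = 1.31e-05, adjusted p = 0.72 with an estimated correlation). Of 13 genes of the intracellular pathogen response 4 rose on bcat-1 RNAi and 7 adjusted over the list alone, with the Skp1-related gene skr-4 at 0.88 (camera adjusted p = 2.31e-06, adjusted p = 0.0902 with an estimated correlation).

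Amino acid enzymes outside the branched-chain path were compared too. On bcat-1 RNAi the proline breakdown gene alh-6 (-0.50), the transaminase gene gta-1 (-0.59) and the phenylalanine hydroxylase gene pah-1 (-0.51) fell; of 24 members of that list 9 fell over all genes and 13 adjusted over the list alone (median -0.41, camera adjusted p = 8.08e-09, adjusted p = 0.0902 with an estimated correlation). TCA and glyoxylate cycle genes were negative in 28 of 28 members, with 3 that fell over all genes and 15 adjusted over the list alone (camera adjusted p = 3.79e-09, adjusted p = 0.182 with an estimated correlation).

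After group means were removed, the log2 CPM of L4440 day 2 replicate 1 was closest to bcat-1 day 2 replicate 1 (r across genes 0.72) and L4440 day 2 replicate 2 to bcat-1 day 2 replicate 2 (0.73), each the closest of the other. L4440 day 2 replicate 3 was closest to bcat-1 day 2 replicate 3 (0.29), which was closest to bcat-1 day 1 replicate 1 (0.35). L4440 day 1 replicate 3 was closest to bcat-1 day 1 replicate 3 (0.50), which was closest to bcat-1 day 2 replicate 1 (0.51). The other day 1 libraries were each closest to a day 2 library (0.27 to 0.43). Genes are not independent replicates, the replicate numbers come from no label, and no pairing was assumed. Major sperm protein genes had 0 tested members.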
